A study of Homo sapiens with 6 samples.

How the data were processed

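The series holds 6 arrays of RPE cells derived from human embryonic stem cells, 3 taken 5 days and 3 taken 14 days after splitting. The groups and replicate numbers were taken from the sample descriptions, and each column of the value table was matched to its sample by name. The deposited values are on a log2 scale, and were made with RMA in Affymetrix Expression Console, per the submitters' processing notes, which name no versions. RMA comprises a background correction, quantile normalization between arrays and a summary of the probes of a probe set, so that differences in total RNA between days cannot be seen in such values and a shift of most genes in the same direction would be partly removed. The values carry 2 decimals. No genome build is given in the sources used here, so no coordinates are reported. Scanner files, detection p-values and scan dates were not used here, so neither background per array nor a batch could be tested, and signal over background limits what can be said of dim probe sets.

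The table has 33297 probe sets. In the platform annotation, 19460 have a single gene symbol, 1754 have several and 12083 have none listed. No gene was named from a probe set with several symbols. Of the probe sets with a single symbol, 19429 matched a RefSeq reference table by gene ID, which changed 0 symbols. A gene was represented by the probe set with the highest mean over the 6 arrays among those that name it alone, which gave 18417 genes, 769 of them with more than 1 probe set. Array control probe sets were meant to be left out, but the identifiers do not mark them, so all probe sets stayed in the tests.

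The days were compared on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the day as the only term and all 6 arrays in the fit. P-values were adjusted by the Benjamini-Hochberg method over all 33297 probe sets, and 0.05 was the threshold. Standard errors are those of the moderated fit, and SDs are between the 3 arrays of a day. Adjusted over the list alone means the same adjustment over the genes of a list. A set of 50 gene lists with 1139 distinct genes was fixed, of which 1050 had a probe set that names them alone in the tables used here. The others, among them DCT, RDH5, POU5F1, NANOG and the HLA class I genes, were not analysed here. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 50 lists. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the plots.

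The rule for the genes to be named was fixed before the data were examined, as were the design, the lists and the alternatives, except where the text says otherwise. It took the 12 largest rises and the 12 largest falls among genes that passed and whose arrays did not overlap between days, leaving out XIST, Y-linked genes, small non-coding RNAs and uncharacterised loci. It further took up to 4 members of each list that passed, by smallest adjusted p, or 2 by smallest p where none did, and 10 genes whatever their values (MITF, OTX2, PAX6, RPE65, RLBP1, BEST1, TYR, MKI67, VIM and ACTA2). The text names a part of these.

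The alternatives were the replicate number as a block, leaving out each array in turn, keeping the probe sets above the median level, an intensity trend in the prior variance, array weights, another quantile normalization, centring each array on its median, requiring a change of at least 2-fold, the mean of all probe sets of a gene, camera with a correlation estimated for each list, and fry. Chosen after seeing the data were a fit on the annotated probe sets alone, camera with the trend of the difference with level removed, and a fit with the array mean of 28 long transcripts as a covariate.

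The fit was tested on simulated data with the means and residual SDs of the 33297 real probe sets, of which 200 were changed by known amounts. For day 14 against day 5, limma called 72% of the probe sets changed by 1 on the log2 scale, 88% of those changed by 2, 90% of those changed by 3 and 98% of those changed by 4, each in the right direction, and 11 unchanged ones. In a second simulation camera called 10 of 10 lists of 20 probe sets shifted by 1 and 0 of 40 unshifted lists. The simulated values varied independently in both, so the second result does not cover lists whose genes vary together. Nor does the first cover arrays that deviate as a whole. It changed 200 probe sets, against 7199 that passed in the real data, so its shares need not hold there.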

Results

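Gene expression was measured in retinal pigment epithelium (RPE), the pigmented cell layer that lies behind the photoreceptors, grown in culture from the human embryonic stem cell line labelled Hes1. The cells had been differentiated with nicotinamide and activin A, kept 6 to 10 weeks in suspension, plated for 3 to 5 weeks in medium with 10 mM nicotinamide and then passaged every 2 weeks. Polyadenylated RNA was taken 5 or 14 days after the cells were split, labelled with biotin and hybridised to 6 single-colour Affymetrix arrays, 3 per day. Each array gave log2 values for 33297 probe sets, of which 19460 named a single gene. These covered 18417 genes. The study describes its triplicates as independent, and the labels do not say whether they were separate cultures, so p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision.

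The medians of the 6 arrays lay between 6.90 and 7.03 on the log2 scale. Across probe sets, which are not independent replicates, Pearson's r was 0.989 to 0.995 between arrays of day 5, 0.970 to 0.992 between arrays of day 14 and 0.938 to 0.974 between days. The first principal component held 68.9% of the variance and separated the days. The second held 18.7% and set replicate 1 of day 14 apart from the other arrays. Replicate 1 of day 5 and replicate 1 of day 14 were the arrays of their days nearest to the other day on the first component.

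**Figure D1:**
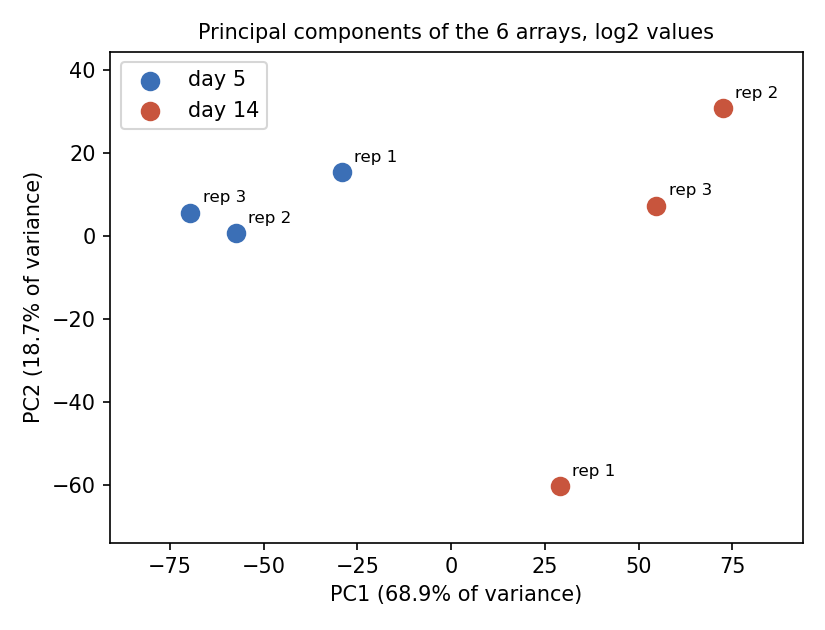
Scores of the 6 arrays on the first 2 principal components of the log2 values, 1 point per array, with the share of variance on each axis. Day 5 arrays lie between -69.56 and -29.15 on the first component and day 14 arrays between 29.01 and 72.41, and replicate 1 of day 14 lies at -60.24 on the second.

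The comparison asks which genes differed in RPE cells between 14 and 5 days after splitting. Some genes of RPE function, among them BEST1, RPE65, RLBP1 and AQP1, were higher at day 14, while others fell or did not pass. Genes of DNA replication and mitosis were lower. With limma, 5282 of 18417 genes (28.7%) differed at an adjusted p under 0.05, 2509 of them higher and 2773 lower at day 14. Falls were larger than rises, since 486 genes rose and 1269 fell by at least 2-fold. Counted by probe set, 7199 of 33297 passed, 3538 higher and 3661 lower, and 590 and 1613 of these differed by at least 2-fold. The 3 arrays of each day did not overlap for 44.7% of probe sets, where chance gives 10%. The median difference over all genes was 0.11 on the log2 scale, and the lists described further on are to be read against it. The count depended on which arrays were in the fit. It was 1702 genes without replicate 2 of day 5 and 1792 without replicate 3 of day 5. Without replicate 3 of day 14 it was 2132, without replicate 2 of day 14 3010, and without replicate 1 of day 5 4632. The counts within the gene lists described below also depended on the arrays kept. Summed over 50 lists, 476 members passed, against 225 and 234 without replicates 2 and 3 of day 5 and 311 and 263 without replicates 2 and 3 of day 14, and in 44, 43, 32 and 40 of the lists, in the same order, the count shrank by over 1.5 times. Without replicate 1 of day 14, where 7216 genes passed, 548 members did, and the count grew by over 1.5 times in 7 lists and shrank so in 1. Without replicate 1 of day 5, 438 did, and it shrank so in 4 lists and grew in 2. Of 207 named genes that passed, 71, 66, 41 and 53 did not pass in the fits without replicates 2 and 3 of day 5 and replicates 2 and 3 of day 14. With each array centred on its own median, 38.9% of the changed genes were higher, against 47.5% as deposited.

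The 12 largest rises were led by RNASE1, a secreted ribonuclease, which rose by 4.32 ± 0.21 (log2 difference ± SE, n = 3 per day, adjusted p = 0.000772), from 8.13 ± 0.28 to 12.45 ± 0.31 (mean ± SD). OC90, an otoconial matrix protein, rose by 4.04 ± 0.34, and OPCML, a cell adhesion molecule, rose from 6.21 ± 0.33 to 10.21 ± 0.27. Transport genes among them were ATP1B2, a sodium pump subunit, at 3.74 ± 0.21, the zinc transporter SLC39A12 at 3.60 ± 0.32 and the water channel AQP1 at 3.58 ± 0.43. Matrix and secreted proteins were SMOC2 at 3.72 ± 0.27, IGFBP5 at 3.32 ± 0.26 and PRELP at 3.31 ± 0.10. The others were CNGB3, known as a cone channel subunit, at 3.50 ± 0.50, GNB3, known as a cone G protein subunit, at 3.28 ± 0.25, and BCO1, which cleaves beta-carotene to retinal, at 3.28 ± 0.38. Their adjusted p lay between 0.000545 for PRELP and 0.00755 for CNGB3.

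Most of the 12 largest falls were of genes of cell division. DLGAP5, a spindle protein, fell by 4.15 ± 0.18 (adjusted p = 0.000545), from 9.42 ± 0.30 to 5.27 ± 0.17, and ANLN, a scaffold of the cleavage furrow, fell by 4.04 ± 0.17. CEP55, of the midbody, fell by 3.99 ± 0.23, ESCO2, a cohesin acetyltransferase, fell by 3.96 ± 0.28, and SMC2, a condensin subunit, fell by 3.80 ± 0.34. NUF2 of the kinetochore had a log2 difference of -3.77, the checkpoint kinase TTK -3.76, SGO1, which protects centromeric cohesion, -3.72, DEPDC1 -3.67, the kinesin KIF23 -3.60 and the kinase CDK1 -3.59. DKK1, a secreted Wnt antagonist, was the exception, with a fall of 3.78 ± 0.22. The adjusted p of these genes lay between 0.000545 and 0.00215.

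Genes of RPE identity moved apart. RPE65, the isomerase of the visual cycle, rose by 2.25 ± 0.27, from 5.91 ± 0.45 to 8.16 ± 0.34 (adjusted p = 0.00462). RLBP1, a retinaldehyde carrier, rose by 2.28 ± 0.28, and BEST1, a chloride channel of the basolateral membrane, by 3.18 ± 0.24. TYR, the enzyme that starts melanin synthesis, rose by 1.02 ± 0.21. OTX2, a transcription factor of the RPE, rose by 0.84 ± 0.12, while PAX6, an eye field transcription factor, fell by 0.63 ± 0.13. MITF, the master regulator of pigment cells, had a difference of 0.39 ± 0.17 that did not pass (adjusted p = 0.142), at levels of 10.58 ± 0.17 and 10.97 ± 0.29. Of 16 RPE transcription factors, 6 rose and 3 fell (7 and 4 adjusted over the list alone), SOX9 by 1.98 ± 0.10, CRX by 2.51 ± 0.31 and SIX3 by 1.10 ± 0.11 being among those that rose. As a list they did not pass camera, a test of whether the genes of a list moved relative to all other genes (adjusted p = 0.289).

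**Figure D2:**
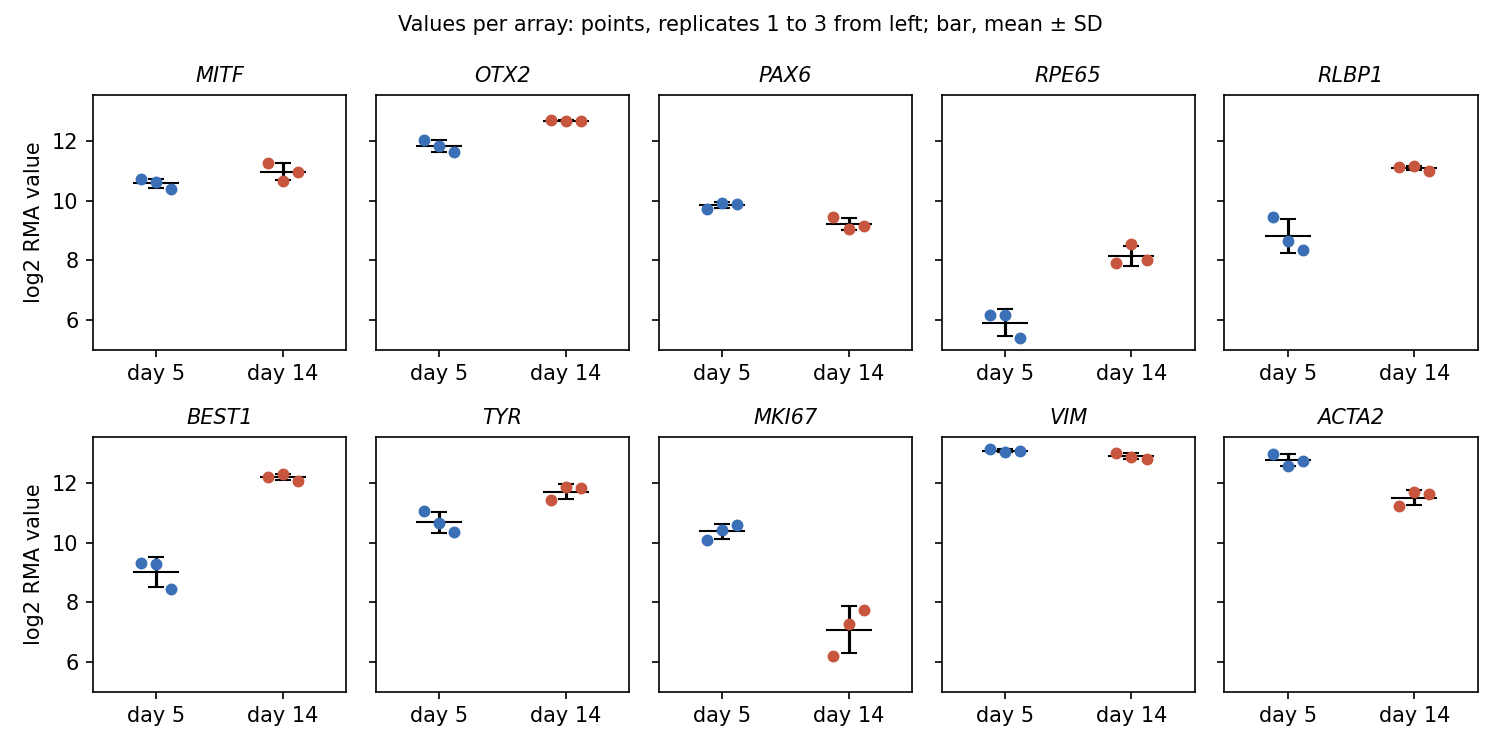
Log2 values of 10 genes chosen for report whatever their values, with 1 point per array, replicates 1 to 3 from left to right, and bars for the mean ± SD of 3 arrays. RPE65, RLBP1, BEST1, TYR and OTX2 lie higher at day 14, PAX6, MKI67 and ACTA2 lie lower, and MITF and VIM did not pass the test.

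Of 5 lists for functions of the mature RPE, those of transport and of melanosomes were called higher at day 14 by camera, and the other 3 were not. Among 26 measured genes of RPE ion and solute transport, 12 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.57. The 12 became 6 without replicate 2 of day 5, 5 without replicate 3 of day 5 and 7 without replicate 2 or 3 of day 14, and with the array mean of 28 long transcripts, described with the cell cycle genes, as a covariate the median was 0.231. KCNJ13, a potassium channel, rose by 2.48 ± 0.20 and the carbonic anhydrase CA14 by 2.86 ± 0.32. Camera called the list higher (adjusted p = 0.00221), but not with an estimated correlation between its genes (adjusted p = 0.473 with an estimated correlation). In the melanosome and melanin synthesis list, 11 of 21 genes rose and 2 fell (14 and 2 adjusted over the list alone). The 11 became 5 without replicate 2 of day 5 or replicate 3 of day 14 and 7 without replicate 3 of day 5. SLC24A5, an ion exchanger of the melanosome, rose by 1.29 ± 0.09, TYRP1 by 1.12 ± 0.14 and OCA2 by 1.33 ± 0.17, while QPCT, glutaminyl cyclase, fell by 1.34 ± 0.12. This list was called higher (adjusted p = 0.0187, and adjusted p = 0.537 with an estimated correlation). Over 15 other settings its adjusted p lay between 0.00120 and 0.0971, and the call was lost with the long transcripts as a covariate.

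Visual cycle and retinoid genes had 7 of 16 members higher and 1 lower (7 and 1 adjusted over the list alone). Besides RPE65, the opsin RGR rose by 2.40 ± 0.13, the retinol receptor STRA6 by 2.60 ± 0.28 and the acyltransferase LRAT by 1.40 ± 0.14. The list did not pass (adjusted p = 0.0540), and 8 of 15 other settings called it, over a range of 0.00224 to 0.106. These were the fits without replicate 2 or 3 of day 5 or replicate 3 of day 14, on bright probe sets alone, with each array centred on its median, with the mean of all probe sets of a gene, with the trend with level removed and with the long transcripts as a covariate. Secreted RPE factors, with 11 of 21 genes higher and 4 lower (14 and 4 adjusted over the list alone), did not pass either (adjusted p = 0.0578), though 5 of 15 other settings called them, among them those without replicate 2 or 3 of day 5, where 6 and 7 genes were higher. Prostaglandin D synthase, PTGDS, rose by 1.65 ± 0.12, cystatin C, CST3, by 1.48 ± 0.15 and BMP7 by 2.71 ± 0.27. Genes of the phagocytosis of outer segments went both ways, 5 of 16 higher and 3 lower (5 and 4 adjusted over the list alone, adjusted p = 0.587). The receptor MERTK rose by 1.59 ± 0.10 and the motor MYO7A by 1.34 ± 0.24, whereas AXL, a receptor of the same family as MERTK, fell by 0.90 ± 0.13.

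Cell cycle genes fell together. All 39 measured genes of the mitosis list were lower at day 14 (39 adjusted over the list alone), with a median of -2.79, or 6.90-fold. KIF11, a spindle motor, fell by 3.27 ± 0.16, and MKI67, the proliferation marker Ki-67, fell by 3.30 ± 0.39, from 10.38 ± 0.26 to 7.09 ± 0.79. Of 38 genes of DNA replication, 35 fell and none rose (35 adjusted over the list alone), with a median of -1.70, or 3.25-fold. Cyclin E2, CCNE2, fell by 3.14 ± 0.14 and the helicase subunit MCM4 by 1.90 ± 0.14. Camera called the mitosis list (adjusted p = 1.01e-27, and adjusted p = 0.432 with an estimated correlation) and the replication list (adjusted p = 8.00e-22, and adjusted p = 0.432 with an estimated correlation). Replication-dependent histones had 7 of 23 genes lower and 0 higher (9 lower adjusted over the list alone), among them H2BC14 by 1.01 ± 0.20 and H3C8 by 0.88 ± 0.15. The 7 became 4, 1 and 0 without replicates 1, 2 and 3 of day 5 (9 at an unadjusted p under 0.05 in limma where none passed) and 3 and 2 without replicates 2 and 3 of day 14. The list's median in replicate 1 of day 5 lay 0.375 above the other day 5 arrays, against a day difference of -0.257. Without that array the difference was -0.14, with 1 gene higher, and with the long transcripts described below as a covariate it was -0.713. Histone genes are near-identical copies, so single members are uncertain. How fully the polyadenylated RNA taken here samples histone transcripts was not tested, so the fall need not be one of their total amount. Their list was called lower (adjusted p = 0.00951, and adjusted p = 0.745 with an estimated correlation), but not without replicate 1 of day 5, with array weights or among bright probe sets alone, over a range of 7.91e-13 to 0.106.

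The list of cell cycle inhibitors went both ways, with 6 of 16 higher and 3 lower (6 and 4 adjusted over the list alone, adjusted p = 0.795). CDKN1B, the inhibitor p27, rose by 0.87 ± 0.09 and the antiproliferative gene BTG1 by 0.81 ± 0.12. GAS2L3, a member of the list but a cytoskeletal linker active in cell division, fell by 2.56 ± 0.21, so its fall need not be that of an inhibitor. Targets of p53 included 3 of 22 genes that rose and 5 that fell (3 and 6 adjusted over the list alone, adjusted p = 0.0592). The death receptor FAS fell by 1.47 ± 0.26 and the cytokine GDF15 rose by 0.93 ± 0.20.

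Beside these falls stood a difference between arrays that did not follow the day alone. In 28 long transcripts of large coiled-coil and nuclear proteins, a list chosen after some of their values were seen, 19 were lower at day 14 and the median difference was -1.39. Transcript lengths were not measured here, so the name of the list is a label and not a tested trait. The list's median relative to the day 5 mean was -0.59, 0.20 and 0.38 in day 5 replicates 1, 2 and 3, and -1.03, -1.66 and -1.63 in the day 14 replicates. All 28 were lower in replicate 1 of day 5 than in the other arrays of that day.

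**Figure D3:**
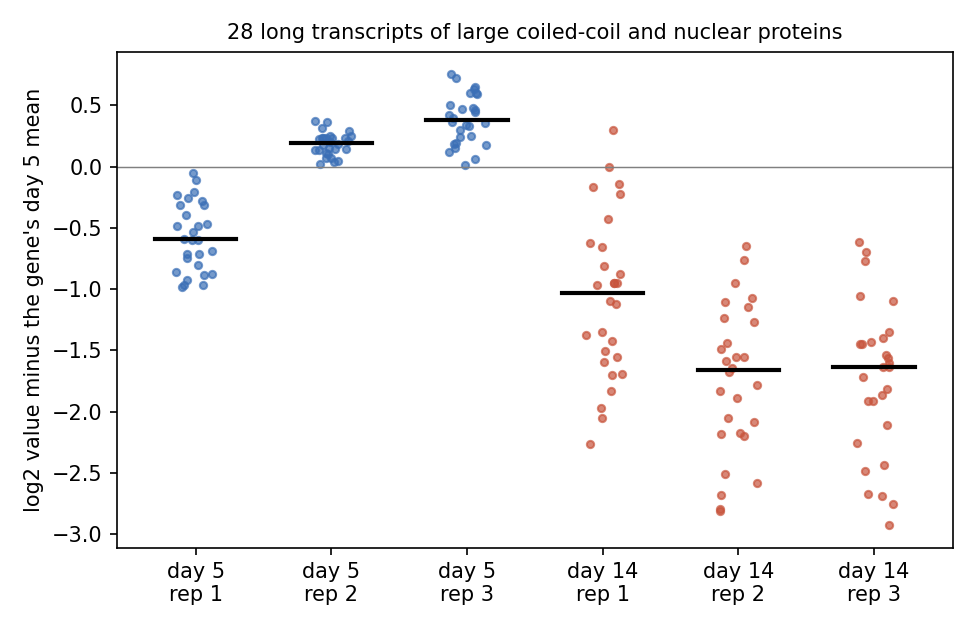
Log2 value minus the gene's day 5 mean for 28 long transcripts, 1 point per gene and array, with a bar at each array's median. Replicate 1 of day 5 has a median of -0.59, below the other day 5 arrays, and replicate 1 of day 14 a median of -1.03, above the other day 14 arrays.

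Genes of the contractile cytoskeleton and of simple epithelia were lower at day 14. In the actin and contractile list, 16 of 23 genes fell and 0 rose (18 lower adjusted over the list alone), with a median of -0.80. ACTA2, smooth muscle actin, fell by 1.25 ± 0.17, caldesmon, CALD1, by 1.95 ± 0.19 and tropomyosin TPM4 by 1.81 ± 0.16. Camera called the list lower (adjusted p = 3.41e-10, and adjusted p = 0.432 with an estimated correlation). Among targets of the transcription factors YAP and TEAD, 14 of 24 fell and 2 rose (16 and 2 adjusted over the list alone), with CCN2 changed by -1.13 ± 0.10 and TEAD1 itself by -1.42 ± 0.17. Without replicate 2 or 3 of day 5, 9 fell. This list was also called (adjusted p = 1.71e-05, and adjusted p = 0.432 with an estimated correlation). The simple epithelial keratins and intermediate filaments had 10 of 17 members lower and 0 higher (13 lower adjusted over the list alone). Without replicate 3 of day 14, 6 were lower. KRT7 fell by 1.92 ± 0.13, KRT19 by 1.74 ± 0.09 and lamin B1, LMNB1, by 1.45 ± 0.14, and the list was called (adjusted p = 1.71e-05, and adjusted p = 0.432 with an estimated correlation).

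Markers of epithelial-mesenchymal transition did not move as a list (adjusted p = 0.401), with 3 of 16 higher and 4 lower (3 and 4 adjusted over the list alone). TGFBI, a secreted matrix protein, fell by 2.19 ± 0.26, the repressor ZEB1 fell by 0.73 ± 0.18 and SNAI1 rose by 0.33 ± 0.08. Vimentin, VIM, had a difference of -0.19 ± 0.09 that did not pass (adjusted p = 0.165). Epithelial junction and polarity genes divided into 5 of 24 higher and 4 lower (7 and 5 adjusted over the list alone, adjusted p = 0.832). P-cadherin, CDH3, rose by 2.31 ± 0.24, CLDN19, a claudin of the RPE, by 1.87 ± 0.26 and CLDN3 by 1.57 ± 0.23, and EPCAM fell by 0.93 ± 0.15.

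Extracellular matrix genes went in both directions, and none of their 3 lists passed. Fibrillar collagens and interstitial matrix had 9 of 31 genes higher and 8 lower (13 and 9 adjusted over the list alone, adjusted p = 0.827). Biglycan, BGN, rose by 2.36 ± 0.26 and COL6A1 by 1.08 ± 0.10, and COL5A2 fell by 1.02 ± 0.13. In the basement membrane list, 5 of 23 rose and 4 fell (7 and 4 adjusted over the list alone, adjusted p = 0.714). Here NID2 rose by 0.98 ± 0.17, whereas collagen COL4A1 fell by 1.19 ± 0.12 and laminin LAMA1 by 1.42 ± 0.14. Matrix proteases and inhibitors had 5 of 23 genes higher and 5 lower (5 and 5 adjusted over the list alone, adjusted p = 0.832). The urokinase PLAU fell by 1.51 ± 0.15, its receptor PLAUR by 1.95 ± 0.23 and ADAMTS5 by 2.06 ± 0.25.

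Signalling genes changed within most pathways, mostly without a shift of the list. For the Wnt pathway, 9 of 29 genes rose and 3 fell (13 and 3 adjusted over the list alone, adjusted p = 0.0540), and 6 of 15 other settings called the list higher, among them those without replicate 2 or 3 of day 5. The secreted antagonists FRZB, SFRP1 and SFRP5 rose by 2.89 ± 0.30, 1.34 ± 0.16 and 1.30 ± 0.21, in contrast to DKK1. BMP pathway genes were higher in 3 of 22 cases and lower in 7 (6 and 9 adjusted over the list alone, adjusted p = 0.0799). The ligand BMP7 and its antagonist NOG, at 1.57 ± 0.18, rose, while the BMP target genes ID1 and ID4 fell by 2.53 ± 0.28 and 1.05 ± 0.10. TGF-beta pathway genes had 4 of 21 higher and 6 lower (5 and 6 adjusted over the list alone, adjusted p = 0.610), with LTBP1 higher by 1.34 ± 0.16 and the inhibitory SMAD7 lower, at -0.97 ± 0.10. In the Notch list 6 of 19 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.123). NOTCH3 rose by 0.69 ± 0.07 and the target gene HES1 fell by 0.68 ± 0.10. Besides the YAP and TEAD targets given above, immediate early genes were the only signalling list called. They were lower at day 14 with 8 of 24 falling and 3 rising (8 and 4 adjusted over the list alone, adjusted p = 0.0347, and adjusted p = 0.584 with an estimated correlation). The 8 falls became 5 without replicate 1 of day 5 and 4 without replicate 2 or 3 of either day. The phosphatase DUSP1 fell by 1.67 ± 0.11 and MYC by 1.15 ± 0.09, but DUSP4 rose by 2.51 ± 0.15. Over 15 other settings the adjusted p of this list lay between 0.0166 and 0.218, and 8 called it. It was not called without replicate 1 of day 5, without replicate 2 or 3 of day 14, among bright probe sets alone, after another quantile normalization, with the trend with level removed or with the long transcripts as a covariate.

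Among metabolic lists, camera called glycolysis higher and cholesterol synthesis lower. Of 21 glycolysis genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone), with PFKFB4 higher by 0.87 ± 0.10, aldolase C, ALDOC, by 1.36 ± 0.23 and the glucose transporter SLC2A3 by 1.01 ± 0.18. The 10 rises became 3 without replicate 2 or 3 of day 5, 5 without replicate 2 of day 14 and 2 without replicate 3 of day 14. The list was called higher (adjusted p = 0.0240, and adjusted p = 0.594 with an estimated correlation). Its adjusted p lay between 0.00172 and 0.557 over 15 other settings, the highest with the long transcripts as a covariate, where it was not called and the median was 0.0285 against 0.44 without it. Hypoxia-response genes had 12 of 22 members higher and 1 lower (13 and 5 adjusted over the list alone, adjusted p = 0.0958), and 3 of 15 other settings called the list. The 12 became 2 without replicate 2 or 3 of day 5, 5 without replicate 2 of day 14 and 6 without replicate 3 of day 14. ANGPTL4 rose by 2.14 ± 0.24 and VEGFA by 1.29 ± 0.21, and HIF1A, the oxygen-regulated transcription factor subunit, fell by 1.64 ± 0.15. Cholesterol synthesis and uptake genes were lower in 10 of 19 cases and higher in 2 (10 and 2 adjusted over the list alone). HMGCS1, an early enzyme of the pathway, fell by 1.81 ± 0.19 and squalene epoxidase, SQLE, by 1.15 ± 0.15. Camera called this list lower (adjusted p = 0.00446, and adjusted p = 0.473 with an estimated correlation).

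Other metabolic lists did not pass. Fatty acid oxidation had 7 of 23 genes higher and 4 lower (8 and 4 adjusted over the list alone, adjusted p = 0.307). The regulators PPARA and PPARGC1A rose by 1.36 ± 0.16 and 1.08 ± 0.13, and OXCT1, an enzyme of ketone use, fell by 1.31 ± 0.11. Oxidative phosphorylation had 1 of 32 genes higher and 4 lower (1 and 1 adjusted over the list alone, adjusted p = 0.744), with NDUFB5 at 0.45 ± 0.09 and NDUFA5 at -1.03 ± 0.27. Replicate 1 of day 14 had a median of -0.455 against the other day 14 arrays in this list, and without it 6 genes were higher and 4 lower, the median was 0.202 against 0.045, and the direction of camera turned from lower to higher (adjusted p = 0.406). Without replicate 1 of day 5, 1 was higher and 1 lower. With the long transcripts as a covariate the list was called lower (adjusted p = 0.00316). Of 20 genes of NAD and nicotinamide metabolism, 3 rose and 2 fell (4 and 3 adjusted over the list alone, adjusted p = 0.970). Without replicate 1 of day 14, 7 were higher and 4 lower, and without replicate 2 or 3 of day 5 none passed in limma (6 and 5 at an unadjusted p under 0.05). The mitochondrial adenylyltransferase NMNAT3, which forms NAD, rose by 0.90 ± 0.15 and PARP1, which consumes NAD, fell by 0.58 ± 0.15.

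Among heat shock proteins 9 of 18 fell and 0 rose (10 lower and 1 higher adjusted over the list alone), with HSP90AA1 changed by -2.19 ± 0.16 and HSPH1 by -1.96 ± 0.16. The 9 became 4 without replicate 2 or 3 of day 5 and 5 without replicate 3 of day 14. The list was called lower (adjusted p = 0.000589, and adjusted p = 0.432 with an estimated correlation). Unfolded protein response genes had 1 of 24 higher and 5 lower (1 and 5 adjusted over the list alone, adjusted p = 0.307), including HSP90B1, an endoplasmic reticulum chaperone, at -1.06 ± 0.16. For lysosome and autophagy genes the numbers were 7 of 29 higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.375), with acid glucosidase GAA at 1.05 ± 0.16 and the proton pump subunit ATP6V1H at -0.76 ± 0.08. Antioxidant genes had 3 of 25 higher and 4 lower (3 and 4 adjusted over the list alone, adjusted p = 0.765). Heme oxygenase, HMOX1, rose by 1.79 ± 0.23 and thioredoxin, TXN, fell by 1.31 ± 0.11. MT1X, which rose by 0.56 ± 0.10, was the single member of 9 metallothioneins that passed (1 adjusted over the list alone, adjusted p = 0.320), and these genes also resemble each other closely. Ribosomal protein genes had 3 of 27 higher and 0 lower (3 higher adjusted over the list alone, adjusted p = 0.316), with RPL32 at 0.67 ± 0.14.

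Complement genes were higher in 8 of 17 cases and lower in 0 (10 and 1 adjusted over the list alone), and CFI, which cleaves activated complement, rose by 1.29 ± 0.10, C2 by 1.23 ± 0.10, C1R by 1.30 ± 0.17 and clusterin, CLU, by 1.27 ± 0.16. The list was called higher (adjusted p = 0.0303, and adjusted p = 0.432 with an estimated correlation), but not without replicate 1 of day 5, without replicate 1 of day 14 or with array weights, over a range of 0.000569 to 0.0661. Without replicate 2 or 3 of day 5, 5 genes were higher. Cytokines and chemokines had 3 of 25 genes higher and 4 lower (3 and 4 adjusted over the list alone, adjusted p = 0.160), with IL18 at -3.48 ± 0.22, LIF at -1.90 ± 0.19 and IL33 at 1.73 ± 0.39. Without replicate 1 of day 5, 0 were higher and 7 lower in limma (3 and 10 at an unadjusted p under 0.05), and with the long transcripts as a covariate the median was 0.197 against -0.0967. Interferon-stimulated genes had 4 of 23 higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.832), with IFI6 at 1.08 ± 0.26 and OAS3 at -0.63 ± 0.10. MHC class I presentation had 1 of 11 higher and 2 lower (1 and 2 adjusted over the list alone, adjusted p = 0.832), TAP1 at 0.65 ± 0.12 and ERAP1 at -0.74 ± 0.13.

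Of the lists of markers of other cell types, camera called that of neural retina and neural progenitors and none of the others. Neural retina and neural progenitor markers had 4 of 14 genes higher and 0 lower (7 higher adjusted over the list alone), with a median of 0.35. In limma the 4 became 7 without replicate 1 of day 5 and 0 without replicate 2 or 3 of either day (5 or 6 at an unadjusted p under 0.05). MSI1 rose by 0.55 ± 0.14, the photoreceptor factor NRL by 0.58 ± 0.14 and SIX6 by 0.52 ± 0.14. Camera called this list higher (adjusted p = 0.0133, and adjusted p = 0.537 with an estimated correlation). Over 15 other settings its adjusted p lay between 0.00502 and 0.557, and with the long transcripts as a covariate it was not called. Photoreceptor markers had 8 of 25 higher and 0 lower (8 higher adjusted over the list alone, adjusted p = 0.0540), and 7 of 15 other settings called the list, among them those without replicate 2 of day 5 or replicate 2 or 3 of day 14. Beyond CNGB3, ABCA4, a retinoid transporter, rose by 1.31 ± 0.22 and PRPH2 by 0.53 ± 0.09. Neuron markers had 2 of 18 higher and 4 lower (2 and 4 adjusted over the list alone, adjusted p = 0.832), with MAP2 at -1.61 ± 0.24 and DCX at -1.14 ± 0.19. Pluripotency markers had 4 of 15 higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.307), LEFTY2 at 0.59 ± 0.12 and ZFP42 at -0.72 ± 0.15.

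Of melanocyte and neural crest markers, 1 of 11 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.244), SOX10 at 1.23 ± 0.22 and the receptor KIT at -0.66 ± 0.17. Fibroblast and smooth muscle markers had 4 of 20 higher and 3 lower (6 and 3 adjusted over the list alone, adjusted p = 0.441), with PDPN at 0.67 ± 0.09 and RGS5 at -1.56 ± 0.20. Endothelial markers had 3 of 16 higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.142), with SOX17 at 0.53 ± 0.14 and TEK at -0.60 ± 0.13. Among 14 leukocyte markers CSF1R, the receptor for colony-stimulating factor 1, was the only member that passed (1 adjusted over the list alone, adjusted p = 0.108), with a rise of 2.18 ± 0.46. Lens and surface ectoderm markers had 1 of 18 higher and 0 lower (0 adjusted over the list alone, adjusted p = 0.211), CRYBB1 at 0.29 ± 0.07. Primary cilium genes had 6 of 33 higher and 9 lower (7 and 12 adjusted over the list alone, adjusted p = 0.211), including the transport protein IFT57 at -1.53 ± 0.10 and BBS7 at -1.75 ± 0.23.

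**Figure D4:**
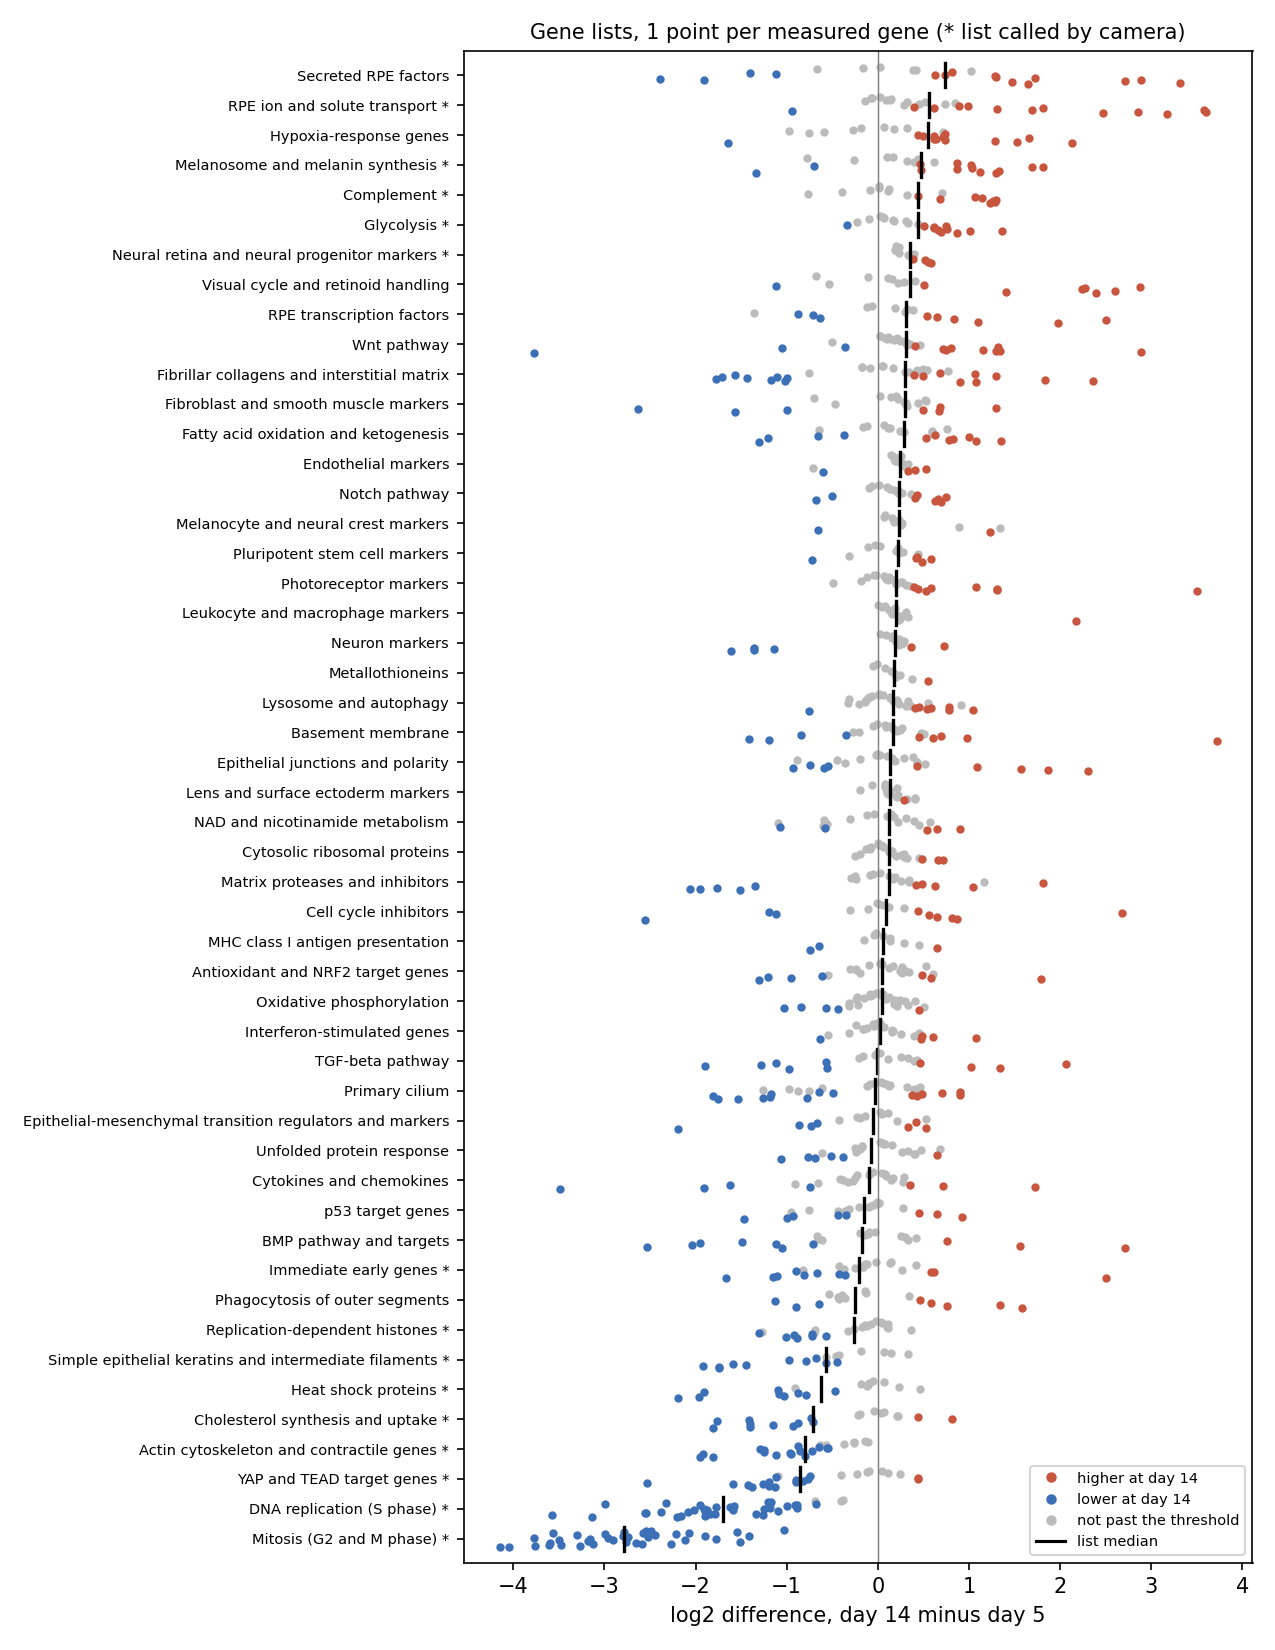
Log2 difference of day 14 minus day 5 for each measured gene of 50 lists, 1 point per gene, with a bar at each list's median. Mitosis, at a median of -2.79, and DNA replication, at -1.70, lie lowest, and 14 lists carry an asterisk for a call by camera with the preset correlation.

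In all, camera called 14 of 50 lists, 5 higher and 9 lower, and 0 with a correlation estimated for each list (4 at an unadjusted p under 0.05). It called 5 to 12 lists in the other 9 ways of splitting the 6 arrays into 3 and 3. Each of those splits mixed the days unequally and so kept a part of the day difference, and their counts give no rate of chance calls. Fry, which asks whether a list's genes move on balance without comparing them with other genes, called 30 lists, 18 higher and 12 lower. The median, the mean and the tests differed in sign for the lists of matrix proteases, MHC class I, oxidative phosphorylation, NAD metabolism, antioxidant genes and neuron markers, and fry and camera did so for phagocytosis. Of the genes named here that had further probe sets of their own, TPM4 had one at -0.23 that did not pass, and those of TYR, EPCAM, C2 and TAP1 passed in the same direction.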

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

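The fits on annotated probe sets alone, with the trend with level removed and with the long-transcript covariate were chosen after the results were seen. No called list or named gene turned its direction under an alternative fixed before the data were examined, and among genes called both as reported and under another fit, 0 were opposite in direction. Calls were less stable. Of 207 named genes that passed, 71 did not without replicate 2 of day 5, 66 without replicate 3 of day 5, 53 without replicate 3 of day 14, 41 without replicate 2 of day 14, 13 without replicate 1 of day 5 and 4 without replicate 1 of day 14. Leaving out single arrays gave 2166 to 10470 probe sets, 1702 to 7216 genes and 11 to 18 lists. The lowest counts came without replicate 2 of day 5 (2166 probe sets and 1702 genes) and without replicate 3 of day 5 (2246 and 1792), followed by replicate 3 of day 14 (2736 and 2132) and replicate 2 of day 14 (3932 and 3010). Fewer arrays account for a part of this, but without replicate 1 of day 14, the array set apart on the second component, the count rose to 10470 probe sets and 7216 genes, of which 4968 were among the 5282. Array weights gave 11503 probe sets, with the lowest weight, 0.348, on that array. The cause of the other differences was not tested.

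Requiring a change of at least 2-fold left 2203 probe sets and 1755 genes by its own construction. Centring each array on its median gave 6211 probe sets and 4569 genes, with 40.7% of the probe sets higher against 49.1% as deposited. It moved the median difference of all genes from 0.11 to 0.10. Camera with an estimated correlation called 0 lists (4 at an unadjusted p under 0.05), against 14 with the preset correlation, and fry called 30. Of the 14 lists, 8 were called under each of 15 other settings that kept the preset correlation. Lists of histones, complement, immediate early genes, glycolysis, melanosomes and neural retina lost the call under at least 1 of them. Others gained one: among these 15 settings, visual cycle genes were called in 8, photoreceptor markers in 7, the Wnt pathway in 6, secreted RPE factors in 5, hypoxia-response genes in 3 and oxidative phosphorylation in 1, lower with the long-transcript covariate (adjusted p = 0.00316).

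With the long-transcript covariate, 0 probe sets and 0 genes passed in limma (4371 probe sets and 2592 genes at an unadjusted p under 0.05), and 12 lists were called, 10 of them as reported. The median of 35 of the 50 lists moved by over 1.5 times or turned its sign, 4 of them called lists (transport, histones, glycolysis and neural retina), and the direction of camera turned in 7 lists, 0 of them called with or without it. The covariate had a correlation of -0.9 with the day and takes up a part of the day difference by its construction. Of 207 named genes that were called as reported, 203 kept their sign with it and 4 did not.

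With the replicate number as a block, 2403 probe sets and 1916 genes passed, 1891 of these also as reported, 17 lists were called, and 64 of the 207 named genes did not pass. The labels do not say that equal numbers share a culture or a day. The deviations of same-numbered arrays from their day's mean had correlations of -0.362, -0.231 and -0.0723, which show no sign of pairing. A shared culture or batch hidden under larger differences between arrays cannot be excluded in this way. No array correlated best with its own number.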

Other observations

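The comparison of replicate 1 with the other arrays of its day in the long transcripts and in the mitosis list, the covariate test of the neural list and its bounds, the families by symbol stem and the list of 28 long transcripts were chosen only after results had been seen. Among 238 families of at least 10 genes grouped by the letters of their symbols, camera called 36, and each family named here had an adjusted p = 0.638 with an estimated correlation. Families that were lower at day 14 included the centrosomal CEP genes, 22 of 37 lower and 1 higher (median -0.96, adjusted p = 2.36e-08), the nucleoporins, 13 of 23 lower and 0 higher (median -0.56, adjusted p = 3.04e-05), the UTP genes of ribosome assembly, 7 of 10 lower (median -0.97, adjusted p = 0.000162) and the SRSF splicing factors, 8 of 12 lower (median -0.57, adjusted p = 0.000765). CEP135 is also among the 28 long transcripts and CEP55 among the largest falls, so the CEP family overlaps with both patterns. Higher at day 14 were the small SCARNA RNAs, 13 of 16 (median 0.68, adjusted p = 0.000162), and the SOX factors, 10 of 19 (median 0.43, adjusted p = 0.00536), while the KRTAP genes of hair were called with a median of 0.23 (adjusted p = 0.00937) although 7 of 68 passed as higher, no larger a share than the 2509 of 18417 among all genes. How fully polyadenylated RNA samples the SCARNA RNAs was not tested. The probe set of the precursor of the microRNA gene MIR204, chosen after its values were seen, lay at 8.31, 8.29 and 7.39 on the day 5 arrays and at 10.55, 6.41 and 7.56 on the day 14 arrays (adjusted p = 0.909).

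The fall of 28 long transcripts of large coiled-coil and nuclear proteins (19 lower, 0 higher, median -1.39, camera p = 9.71e-12, and p = 0.167 with an estimated correlation) is a pattern seen in these data and tested on them. If the arrays differed only in how far the change from day 5 to day 14 had gone, replicate 1 of each day would lie on the same side of the other arrays of its day in this list and in the mitosis list. Replicate 1 of day 5 did so, at -0.887 in the long transcripts and -0.415 in the mitosis list (36 of 39 genes below). Replicate 1 of day 14 did not, at 0.622 in the long transcripts (26 of 28 genes above) and -0.40 in the mitosis list (30 of 39 genes below). The explanation asks for this in both days, so replicate 1 of day 14 goes against it. That rests on 1 array, and the explanation is not excluded. A difference between arrays in RNA yield or quality, apart from the day, remains a candidate explanation, because within day 5 replicate 1 had that median with all 28 genes lower. A biological difference between the cultures of a day, or a real fall with time after splitting, was not tested and stays open.

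The fall of the mitosis list was set against the same difference between arrays. With the array mean of the long transcripts as a covariate the median of the list was -2.75 (quartiles -3.17 and -2.04), against -2.79 without it, and camera still called the list lower (adjusted p = 7.49e-32; 3.76e-19 at the highest over 15 settings that keep the preset correlation), but not with an estimated correlation (adjusted p = 0.517 with it in this fit and 0.432 without the covariate). In this fit 0 of the 39 genes passed in limma, and 35 were lower at an unadjusted p under 0.05. The covariate had a correlation of -0.9 with the day. Against the other arrays of its day, replicate 1 lay at -0.887 on day 5 and 0.622 on day 14 in the long transcripts. In the mitosis list it lay at -0.415 and -0.40, so the days pull the slope of the covariate opposite ways. The fit thus cannot exclude this difference as a cause, though within a day replicate 1 differed far less than the days did. No other technical cause and no biological one was tested for this list.

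The rise of the neural retina and neural progenitor markers was set against a drift of the difference with level. The median difference was 0.05 among the dimmest probe sets, 0.18 among those of middling level and -0.06 among the brightest. The list's median lay at percentile 99.49 of 10000 random lists matched on mean level, whose own median was 0.148. Level alone thus gave a smaller difference in most such lists. The random lists were drawn gene by gene, without the correlation between the list's genes, which was estimated at 0.312. They therefore cannot exclude such a drift as the cause. With the long transcripts as a covariate the median of the marker list was -0.00771 (quartiles -0.04 and 0.20) against 0.35 without it, and the call ended because the difference itself was gone. The covariate and the day had a correlation of -0.9, so the difference between arrays and the day cannot be told apart for this list. A sequence-related cause was not tested.

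Of the 10 ways to split the 6 arrays into 3 and 3, 1, the real one, gave 7199 probe sets and 5282 genes, and the highest of the others gave 0 and 0 with limma (162 to 4229 probe sets at an unadjusted p under 0.05, against 13029). The split with 4229 put replicate 1 of day 5 together with replicates 2 and 3 of day 14. Camera called 14 lists in the real split and 12 in the highest of the others. With 10 splits the share cannot fall under 0.05. Each of the other splits mixed the days unequally. A part of the day difference thus lay between its groups and the rest within them, so these counts do not measure chance. The split with 12 lists set the day 5 replicate 1 and day 14 replicates 1 and 3 against the rest.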
